A study of Homo sapiens with 30 samples.

How the data were processed

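RNA sequencing of LNCaP prostate cancer cells was read from 30 libraries in 10 groups of 3: pLKO control, shUSP7, shBUB3 and shFOXA1; siCtrl and siEZH2; and pGIPZ control, shFoxA1, shFoxA1 + WT and shFoxA1 + K295A. Per the labels, RNA was taken 5 days after shRNA and 4 days after siRNA, although the stated sample range leaves out the third K295A library. The authors deposited FPKM values for the pLKO and siRNA experiments and RPKM values for the pGIPZ experiment. Both were aligned with STAR to hg38 per the submitters' processing notes. FPKM and RPKM scale the reads of a gene by its length and by the library total. The counter, the annotation and the STAR version are not given in the sources used here, and no scaling between libraries beyond the total is stated. Each table held 26475 genes by symbol, of which 32 had no values and were left out, leaving 26443. No pair of columns was identical (0 pairs).

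Neither table holds read totals. Low values are whole multiples of a step set by gene length and library total, so the most frequent ratio of low values between libraries gave relative depth, 0.602 to 1.30 for the FPKM table and 0.847 to 1.30 for the RPKM table. Counting intervals could not be computed without totals, so precision was measured from replicates and on simulated data.

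Values were taken as log2(value + 1). This understates fold changes of genes near or under a value of 1. Genes with a value of at least 1 in at least 3 libraries of a fit were kept. Each experiment had its own fit in limma 3.58.1 (R 4.3.3), with a term per group, an intensity trend and moderated, two-sided tests. Benjamini-Hochberg adjustment ran over the genes tested in each of 8 comparisons, and genes at adjusted p under 0.05 were called. An exact permutation test of 3 against 3 libraries cannot give a p under 0.1, so per-gene statements rest on limma's adjusted p. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 did the remaining steps. Samples, gene lists and the main tests were fixed before the data were examined, as were the alternatives and further tests except where the text says otherwise.

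Of 19 lists fixed from general knowledge, 18 had measured members: androgen-induced genes, luminal prostate identity, epithelial-mesenchymal transition and TGF-beta, mitosis and spindle checkpoint, DNA replication, p53 targets, genes reported as repressed by EZH2, polycomb subunits, neuroendocrine and neuronal markers, interferon response, inflammatory and NF-kB genes, stress response and amino acid synthesis, cholesterol and fatty acid synthesis, hypoxia and glycolysis, forkhead family and cofactors, stromal, immune, basal and endothelial markers, replication-dependent histones, and cytosolic ribosomal proteins. Mitochondrially encoded genes had no measured member. Some genes, such as FOXM1, stand in more than 1 list. Lists were tested with camera in limma against the other genes, with an inter-gene correlation of 0.01, adjusted over all 144 tests of 18 lists and 8 comparisons. Each was repeated with the correlation estimated from the data. In called lists, median, mean and test had the same sign. Members were counted as called over all genes tested and adjusted over the list alone.

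The genes named were set by a rule: USP7, BUB3, FOXA1, EZH2 and KLK3 in every comparison; then the 6 highest and 6 lowest fold changes among called genes with a symbol, a mean of at least 1 in either group and no overlap between the 3 and 3 libraries; then up to 3 called members per list with the largest change in size. For the 3 comparisons of re-expression it took 4 highest, 4 lowest and up to 2 per list. The text gives these fixed genes, the highest and lowest genes with a few left out, and only part of the list members that the rule takes. Gene-level values cannot separate overlapping, antisense or host genes and close paralogs. Positions are from GENCODE 29 (GRCh38), which may differ from the annotation behind the tables.

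Genes called and at least 2-fold changed in a FOXA1 knockdown formed sets that were tested with camera in comparisons from other libraries, adjusted over 12 tests. Overlaps between comparisons with separate controls had two-sided Fisher's exact tests, adjusted over 12 tests. For the comparisons that share the pLKO control, 50 simulated draws of unchanged groups gave the overlap, correlation and covariance that the spread between libraries of the shared control produces. All splits of 3 against 3 libraries into groups of 3 were refitted (10 per comparison).

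Every 7-base word in the longest annotated 3′ UTR per gene (19095 UTRs) that occurred in at least 100 genes was scored against fold changes, with length and base composition removed, and compared with 100 permutations. Words, flanking 8-base sites and 6-base cores were then counted in the transcripts of the targeted gene. Intervals are 95% bootstrap intervals from 10000 draws, or 1000 for word scores.

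The alternatives were a pseudocount of 0.1, no filter on low values, a filter at 5, median-ratio scaling between libraries, a fit of the 2 groups alone, the replicate number as a block, leaving out each replicate, an estimated inter-gene correlation, FOXA1 sets of any fold, and the pGIPZ FOXA1 knockdown in place of that of the pLKO experiment. Alternatives chosen after seeing the data were a size of at least 1.5-fold, a test of the pLKO FOXA1 sets in siEZH2, and the re-expression groups against the pGIPZ control.

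The steps were tested on simulated data with 200 changed genes in each of 5 draws. Of genes simulated at 2-fold, 84.8% to 90.6% were recovered across comparisons, and at 1.5-fold 68.7% to 79.4%. At 1.25-fold, 14.0% to 24.5% were recovered in the pLKO and siRNA experiments and 47.2% to 53.1% in the pGIPZ experiment. False calls made up 2.75% to 9.88% of the calls. A planted set of 40 genes shifted by 0.3 was called in 5 of 5 draws in each comparison, and a set with no shift in 1 of 5 draws in shFOXA1 and 0 elsewhere. A word planted with a shift of -0.1 came out first in 7 of 10 draws in shFOXA1, 9 in shBUB3 and 10 in each other comparison.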

Results

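RNA was sequenced from LNCaP, an androgen-responsive human prostate cancer cell line, in 30 libraries that form 10 groups of 3. In the pLKO experiment, named after the vector, cells carried a control vector or an shRNA against USP7, BUB3 or FOXA1. In the siRNA experiment, a control siRNA was compared with an siRNA against EZH2. In the pGIPZ experiment, also named after its vector, cells carried a control, an shRNA against FOXA1, or that shRNA together with re-expressed wild-type FOXA1 (WT) or a FOXA1 with a lysine replaced by alanine (K295A). USP7 is a deubiquitinase, BUB3 a spindle checkpoint protein, EZH2 the histone methyltransferase of polycomb complex PRC2, and FOXA1 a pioneer transcription factor that opens chromatin for other factors. By its title, the series asks how polycomb proteins and a BUB3 and USP7 complex act on the stability of FOXA1 protein, and these libraries measure RNA only.

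Depth relative to the first pLKO control library was 0.900 to 1.30 in the pLKO experiment and 0.602 to 0.831 in the siRNA experiment. In the pGIPZ experiment it was 0.847 to 1.30 relative to the first control library there. Between 11262 and 12000 genes reached a value of 1 per library. Within groups, log2 values correlated across genes at r of 0.983 or more, and genes are not independent replicates. The third shBUB3 library stood apart, with an FPKM sum of 367614 against 235344 to 306578 in the other libraries of the pLKO experiment. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these samples. Values after ± are SD for levels and SE for log2 fold changes, with n = 3 libraries per group throughout, and p-values are limma or camera values adjusted for multiple tests. Single values in parentheses after a gene are log2 fold changes, and list calls given without a further p also held with an estimated correlation.

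Each targeted RNA was lower in its own knockdown. USP7 (chromosome 16, 8892094 to 8964514, GRCh38) went from 28.2 ± 0.517 to 6.21 ± 0.143 FPKM after shUSP7, a log2 fold change of -2.02 ± 0.052 (adjusted p = 1.1e-10). BUB3 (chromosome 10, 123154277 to 123170467) went from 36.3 ± 2.34 to 4.00 ± 0.629 FPKM after shBUB3, a change of -2.91 ± 0.081 (adjusted p = 1.3e-10). EZH2 (chromosome 7, 148807383 to 148884321) went from 12.6 ± 0.908 to 4.98 ± 0.128 FPKM after siEZH2, a change of -1.18 ± 0.081 (adjusted p = 1.1e-06). FOXA1 (chromosome 14, 37589984 to 37596059) fell in both FOXA1 knockdowns, from 115.8 ± 0.191 to 59.0 ± 1.68 FPKM in the pLKO experiment (-0.96 ± 0.076, adjusted p = 3.9e-07) and from 132 ± 2.38 to 82.5 ± 1.87 RPKM in the pGIPZ experiment (-0.67 ± 0.024, adjusted p = 7.4e-10). The tables were normalized separately, so levels were tested only within a table.

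**Figure D1:**
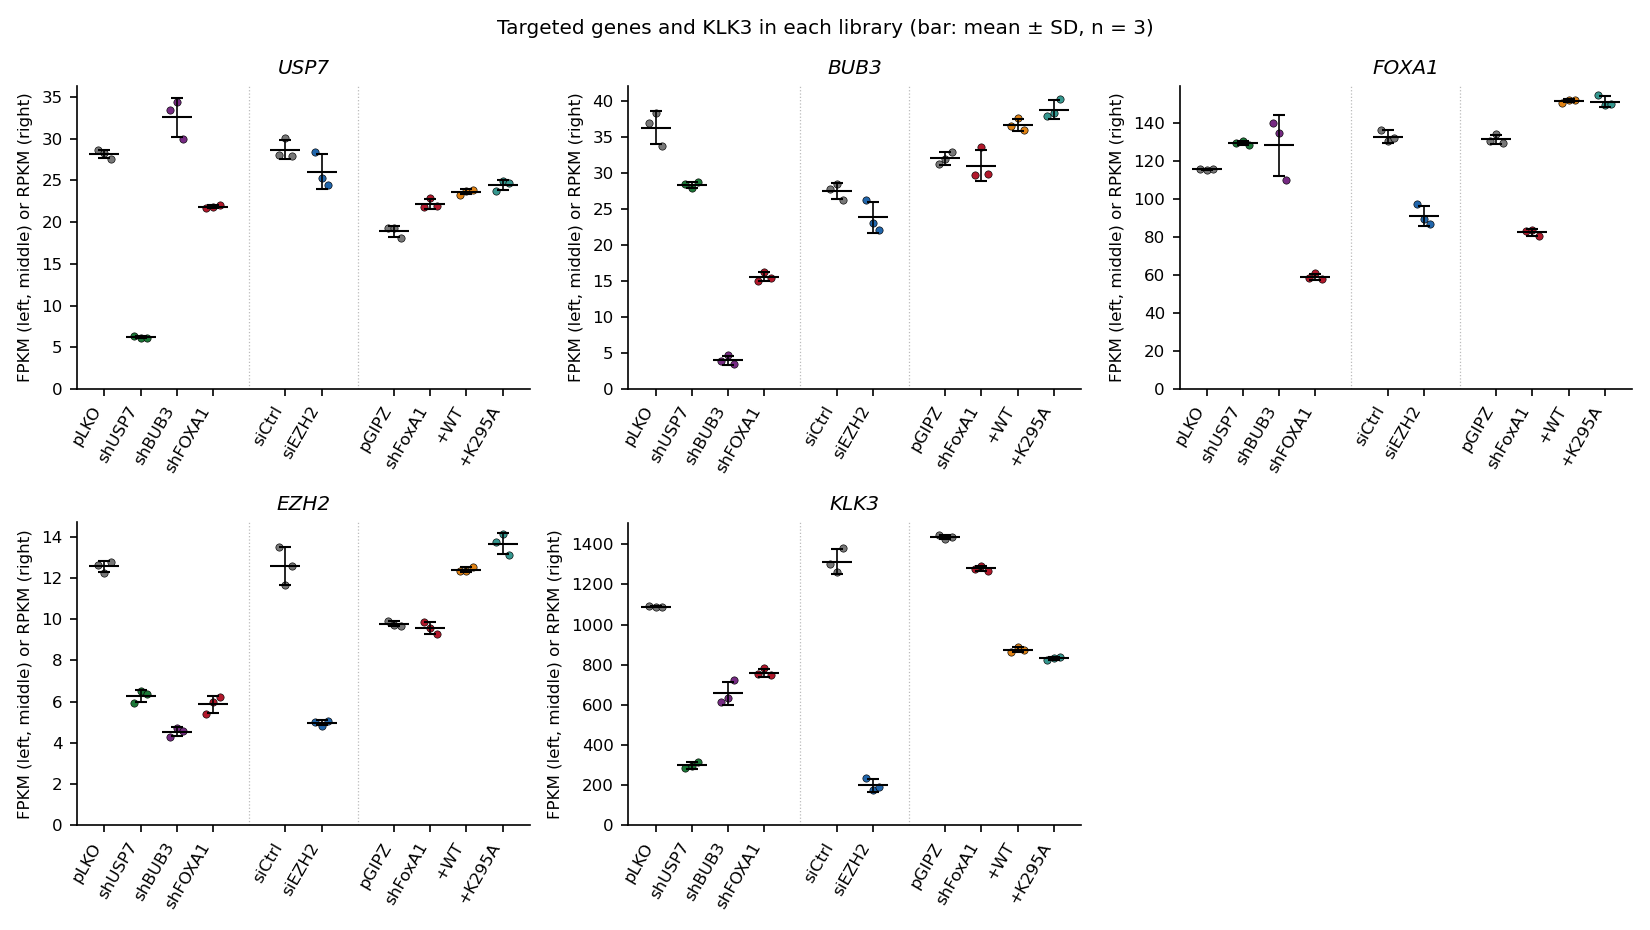
Levels of USP7, BUB3, FOXA1, EZH2 and KLK3 in each library (points) with the group mean and SD (bars), as FPKM for the pLKO and siRNA experiments and RPKM for the pGIPZ experiment. FOXA1 averaged 59.0 FPKM after shFOXA1 against 115.8 FPKM in its control, and 151.8 and 151.4 RPKM after re-expression of WT and K295A.

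To ask what cells do after loss of the deubiquitinase USP7, shUSP7 was compared with the pLKO control. CDKN1A, which encodes the cell cycle inhibitor p21, rose from 93.4 ± 2.86 to 904 ± 14.5 FPKM (3.26 ± 0.066, adjusted p = 4.2e-11). The mitotic genes HMMR (-3.62 ± 0.099), NUSAP1 (-3.56), CDC20 (-3.47) and CCNB2 (-3.44) and the cell cycle transcription factor MYBL2 (-3.58) were among the 6 genes that fell most, with the mitotic kinase PBK (-3.32). HMMR went from 22.8 to 0.936 FPKM. Highest besides CDKN1A were the brush border enzyme SI (4.56), the carrier protein TTR (3.06), the p53 target FDXR (2.90), LRRN1 (2.83) and the arginase ARG1 (2.73). KLK3, which encodes prostate-specific antigen, fell from 1088 ± 3.16 to 299 ± 16.1 FPKM (-1.86 ± 0.078). EZH2 (-0.90) and BUB3 (-0.34) fell too. FOXA1 RNA stood at 129.5 FPKM against 115.8 FPKM (0.16, adjusted p = 0.0856), and it passed the test after median-ratio scaling (0.19, adjusted p = 0.0332) and in a fit of these 2 groups alone (0.16, adjusted p = 0.00054).

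Of the mitosis and spindle checkpoint list, 49 of 50 measured members fell and 1 rose (49 and 1 adjusted over the list alone), with a median of -2.77 and adjusted p = 2.3e-27. In the DNA replication list, 49 of 50 measured members fell and 0 rose (50 and 0 adjusted over the list alone), with a median of -1.62 and adjusted p = 5.5e-22, including RRM2 (-3.31) and TK1 (-2.92), enzymes of nucleotide supply, among the lowest. Among p53 targets, 43 of 46 measured members rose and 2 fell (43 and 2 adjusted over the list alone), with a median of 1.08 and adjusted p = 8.7e-16, led after CDKN1A and FDXR by TP53I3 (2.47). Androgen-induced genes were lower as a list: 32 of 46 measured members fell and 8 rose (33 and 8 adjusted over the list alone), with a median of -0.55, adjusted p = 1.1e-04 and adjusted p = 0.304 with an estimated correlation. KLK2, a kallikrein neighbor of KLK3, went from 112 to 14.3 FPKM (-2.88), while RHOU rose (2.58). In the stress response and amino acid synthesis list, 32 of 43 measured members fell and 4 rose (33 and 5 adjusted over the list alone), with a median of -0.56, adjusted p = 6.7e-06 and adjusted p = 0.129 with an estimated correlation. Its members PHGDH (-2.45) and SHMT2 (-1.57) make serine and glycine, and SLC7A11 (-1.70) imports cystine. In the cholesterol and fatty acid synthesis list, 29 of 38 measured members fell and 5 rose (30 and 5 adjusted over the list alone), with a median of -0.67, adjusted p = 2.0e-06 and adjusted p = 0.0543 with an estimated correlation, including the fatty acid enzymes ELOVL6 (-2.23) and FADS1 (-2.10). In the hypoxia and glycolysis list, 29 of 35 measured members fell and 3 rose (29 and 3 adjusted over the list alone), with a median of -0.59, adjusted p = 4.6e-06 and adjusted p = 0.0547 with an estimated correlation, including NDUFA4L2 (-3.13) and PFKP (-2.54). The other 11 measured lists did not pass (adjusted p from 0.108 to 0.965), although members such as the secreted protein gene AGR2 (-2.72), FOXM1 (-2.95) and the interferon-induced IFITM2 (-2.14) fell and NFKBIZ (2.01) rose.

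In all, 7784 of 12524 genes were called after shUSP7, 3647 higher and 4137 lower, of which 331 and 725 changed at least 2-fold. At 76.6% of the tested genes the 3 and 3 libraries did not overlap, where chance gives 10%.

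BUB3 binds kinetochores in the spindle checkpoint, and its knockdown was compared with the same control. CDC20, the activator of the anaphase-promoting complex, fell from 46.7 ± 2.14 to 1.92 ± 0.321 FPKM (-4.03 ± 0.11, adjusted p = 1.0e-10). The checkpoint gene MAD2L1 (-3.69), HMMR (-3.76), NUSAP1 (-3.76), the microtubule regulator STMN1 (-3.69) and RRM2 (-3.80) fell with it. The genes that rose most were the secreted chaperone gene CLU (3.05 ± 0.14), CDKN1A (2.93), the histone gene HIST1H2BD (2.51), the heat-shock cochaperone gene DNAJB4 (2.26), the androgen-conjugating enzyme gene UGT2B17 (2.20) and TMEM59L (2.18). KLK3 fell from 1088 ± 3.16 to 658 ± 56.6 FPKM (-0.73) and EZH2 fell (-1.29), while USP7 rose (0.20). FOXA1 did not pass the test (0.14, adjusted p = 0.127), and it did without the third shBUB3 library (0.24, adjusted p = 3.4e-05).

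In the mitosis and spindle checkpoint list, 49 of 50 measured members fell and 0 rose (49 and 0 adjusted over the list alone), with a median of -2.92 and adjusted p = 4.1e-29. For DNA replication, 49 of 50 measured members fell and 0 rose (49 and 0 adjusted over the list alone), with a median of -1.77 and adjusted p = 2.0e-23, including CDC45 (-2.88) and TK1 (-2.93). Replication-dependent histones were higher: 19 of 24 measured members rose and 1 fell (19 and 1 adjusted over the list alone), with a median of 1.49 and adjusted p = 2.2e-06. HIST1H2BC (2.13) and HIST1H2BG (1.97) rose, although reads of near-identical histone genes are not told apart with certainty in gene-level values. Of the ribosomal protein genes, 45 of 65 measured members rose and 1 fell (46 and 1 adjusted over the list alone), with a median of 0.39, adjusted p = 3.7e-04 and adjusted p = 0.669 with an estimated correlation, while RPS25 fell (-0.80), and without shBUB3 replicate 3 the list passed with a median of 0.21. Among androgen-induced genes, 37 of 46 measured members fell and 3 rose (37 and 3 adjusted over the list alone), with a median of -0.74, adjusted p = 2.1e-09 and adjusted p = 0.128 with an estimated correlation, including PPAP2A (-2.52) and TSC22D3 (-2.35). Of the p53 targets, 26 of 46 measured members rose and 6 fell (27 and 6 adjusted over the list alone), with a median of 0.31, adjusted p = 0.00253 and adjusted p = 0.0931 with an estimated correlation, including ZMAT3 (1.38) and TP53INP1 (1.22). The stress response list was lower: 26 of 43 measured members fell and 7 rose (26 and 7 adjusted over the list alone), with a median of -0.38, adjusted p = 6.1e-04 and adjusted p = 0.232 with an estimated correlation, including SLC7A11 (-2.13) and MTHFD2 (-1.90). So was the hypoxia and glycolysis list, where 23 of 35 measured members fell and 5 rose (24 and 5 adjusted over the list alone), with a median of -0.41, adjusted p = 0.00116 and adjusted p = 0.141 with an estimated correlation. The remaining 10 measured lists did not pass (adjusted p from 0.145 to 0.902), with the adhesion gene CDH1 (-2.23), the matrix gene FN1 (-3.05) and the desaturase FADS2 (-3.34) among the members that fell.

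After shBUB3, 8168 of 12524 genes were called, 4166 higher and 4002 lower, with 340 and 706 at least 2-fold, and 66.6% of genes without overlap against 10% by chance. Without the third shBUB3 library, 9017 genes were called.

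To ask which genes depend on FOXA1, shFOXA1 was compared with the pLKO control. The small heat-shock protein gene CRYAB rose from 1.93 ± 0.222 to 131 ± 14.004 FPKM (5.49 ± 0.098, adjusted p = 8.2e-12), followed by the IGF-binding protein gene IGFBP3 (4.26), the phospholipase PLA2G2A (4.16), BARX2 (3.98), LINC00930 (3.63) and the matrix gene THBS1 (3.58). SLC45A3, known as prostein, fell from 94.97 ± 0.928 to 3.54 ± 0.588 FPKM (-4.41 ± 0.082). UGT2B17 (-4.47) and UGT2B15 (-3.94), close paralogs whose reads may be shared, fell with TARP (-4.21), PTTG1 (-3.87) and DDC (-3.80). KLK3 fell to 760.5 ± 19.3 FPKM (-0.52, and -0.33 after median-ratio scaling). BUB3 (-1.17, adjusted p = 1.2e-07) and EZH2 (-0.98, adjusted p = 4.1e-08) fell, as did USP7 (-0.35, and -0.17 after scaling).

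Androgen-induced genes were lower as a list: 31 of 46 measured members fell and 10 rose (31 and 11 adjusted over the list alone), with a median of -0.54, adjusted p = 0.0219 and adjusted p = 0.554 with an estimated correlation. SORD, which encodes sorbitol dehydrogenase, fell (-3.21). In the epithelial-mesenchymal transition list, 7 of 14 measured members rose and 4 fell (7 and 4 adjusted over the list alone), with a median of 0.25, adjusted p = 0.0376 and adjusted p = 0.0915 with an estimated correlation, including ID2 (2.99) and ID1 (2.47), and median-ratio scaling ended the call (median 0.41, adjusted p = 0.0936), while with no filter the median was 0. All members of the mitosis list fell: 50 of 50 measured members fell and 0 rose (50 and 0 adjusted over the list alone), with a median of -2.97 and adjusted p = 5.8e-21. For DNA replication, 50 of 50 measured members fell and 0 rose (50 and 0 adjusted over the list alone), with a median of -1.87 and adjusted p = 2.1e-17. In the p53 list, 28 of 46 measured members rose and 9 fell (28 and 9 adjusted over the list alone), with a median of 0.30 and adjusted p = 5.2e-06, with CDKN1A (2.60) higher and PERP (-1.92) lower. Inflammatory and NF-kB genes were higher: 13 of 19 measured members rose and 3 fell (14 and 3 adjusted over the list alone), with a median of 0.67 and adjusted p = 1.0e-04, led by IL32 (2.63), with medians of 0.41, 0.37 and 0.42 without shFOXA1 replicate 1, 2 or 3. Among histone genes, 17 of 24 measured members rose and 6 fell (17 and 6 adjusted over the list alone), with a median of 0.96 and adjusted p = 5.1e-04. Of the cholesterol and fatty acid genes, 27 of 38 measured members fell and 2 rose (27 and 2 adjusted over the list alone), with a median of -0.52, adjusted p = 6.5e-04 and adjusted p = 0.136 with an estimated correlation, including SCD (-2.74) and FADS1 (-2.43). The ribosomal protein list was lower: 65 of 65 measured members fell and 0 rose (65 and 0 adjusted over the list alone), with a median of -0.86, adjusted p = 1.7e-07 and adjusted p = 0.54 with an estimated correlation. Scaling moved the medians of androgen-induced genes to -0.35, p53 targets to 0.46 and cholesterol genes to -0.35 (calls kept). The luminal prostate identity list did not pass (median 0.13, adjusted p = 0.0531, 16 higher and 12 lower of 33, adjusted p = 0.361 with an estimated correlation). At the fixed correlation it passed as higher with a pseudocount of 0.1 (0.16), in a fit of 2 groups (0.13) and without shFOXA1 replicate 1, 2 or 3 (0.17, 0.11 and 0.12). The 9 lists that did not pass (adjusted p from 0.0531 to 0.797) held the corepressor TLE1 (2.62) and CDKN2B (3.48) among the genes that rose.

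Of 12524 genes, 8808 were called, 3158 higher and 5650 lower, with 536 and 1111 at least 2-fold (79.4% without overlap, 10% by chance). Median-ratio scaling moved the median of all genes by 0.157, and the share of called genes that were higher went from 35.9% to 50.1%, with 7488 genes called both ways.

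**Figure D2:**
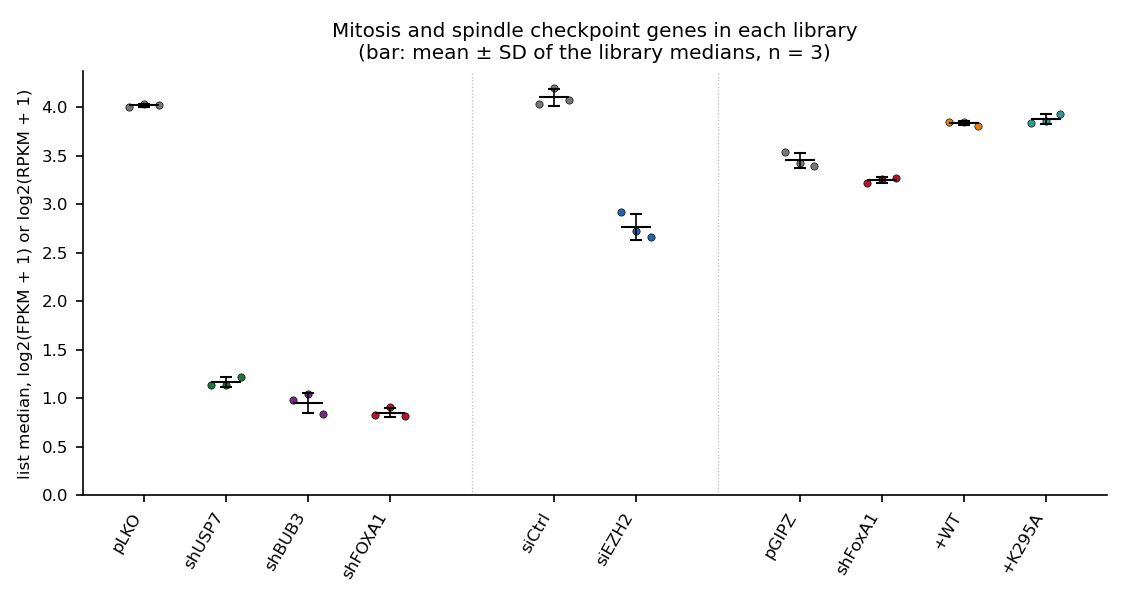
Median over the mitosis and spindle checkpoint list in each library (points, log2 of FPKM or RPKM plus 1) by group. Group means were 4.02 in the pLKO control against 1.17, 0.95 and 0.85 after shUSP7, shBUB3 and shFOXA1, and 3.45 in the pGIPZ control against 3.25 after shFoxA1.

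The knockdowns of the pLKO experiment share a control, which alone correlates their fold changes. After shUSP7 and shBUB3, 2270 genes were lower in both and 1991 higher in both, where independent calls would share 1322 and 1213, and 1329 went opposite ways. For shUSP7 and shFOXA1 the shared counts were 2624 lower and 1505 higher (1866 and 920 if independent), with 1744 opposite. For shBUB3 and shFOXA1 they were 2391 and 1398 (1805 and 1050), with 2278 opposite. Same-sign shares were 65.2%, 61.3% and 56.8%, against 66.6%, 66.7% and 66.6% in unchanged groups simulated with the same control. Fold changes correlated at r of 0.564, 0.465 and 0.404 (simulated 0.495, 0.497 and 0.498). A shared control sets these simulated values, so neither measure decides. Simulated groups shared at most 0.02 calls per draw. Their covariance was 0.00672, 0.00673 and 0.00678 against 0.216, 0.203 and 0.181 in the data, which argues against the control alone. The 3 control libraries are too few to be divided between contrasts.

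EZH2 is the catalytic subunit of PRC2, and its knockdown by siRNA was compared with the control siRNA. KLK3 fell from 1313 ± 60.4 to 201 ± 31.8 FPKM (-2.72 ± 0.10, adjusted p = 4.3e-08) and FOXA1 from 133 to 91.2 FPKM (-0.54, and -0.34 after median-ratio scaling). IGFBP3, a gene reported as repressed by EZH2, rose from 2.44 ± 0.347 to 145 ± 37.0 FPKM (5.38 ± 0.16). Next highest were the tubulin gene TUBA1A (3.88), the bile acid enzyme gene CYP7A1 (3.24), CCDC80 (3.07), HS3ST1 (2.89) and the sestrin gene SESN3 (2.77). The pyruvate kinase gene PKM went from 348 to 43.4 FPKM (-2.99). TARP (-3.40), AZGP1 (-3.15), ST6GALNAC1 (-3.04) and ARF1 (-2.76) also fell. BUB3 was at the threshold (-0.20, adjusted p = 0.0489) and did not pass after scaling (-0.011, adjusted p = 0.901) or without siCtrl replicate 1, 2 or 3 or siEZH2 replicate 2 or 3 (-0.19, -0.18, -0.23, -0.18 and -0.15), nor with a pseudocount of 0.1, no filter or a replicate block (adjusted p = 0.0514, 0.0764 and 0.0567). USP7 did not pass (-0.14, adjusted p = 0.141), turned after scaling (0.053) and passed without siEZH2 replicate 1 (-0.20).

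Androgen-induced genes fell as a list: 42 of 46 measured members fell and 0 rose (42 and 0 adjusted over the list alone), with a median of -1.25, adjusted p = 8.3e-13 and adjusted p = 0.184 with an estimated correlation. In the mitosis list, 50 of 50 measured members fell and 0 rose (50 and 0 adjusted over the list alone), with a median of -1.24, adjusted p = 5.5e-14 and adjusted p = 0.207 with an estimated correlation, including BIRC5 (-2.45) and CENPF (-2.35). For DNA replication, 49 of 50 measured members fell and 0 rose (50 and 0 adjusted over the list alone), with a median of -1.16, adjusted p = 2.7e-12 and adjusted p = 0.19 with an estimated correlation. Of the stress response genes, 33 of 43 measured members fell and 4 rose (33 and 4 adjusted over the list alone), with a median of -0.68 and adjusted p = 3.1e-04, and this call held with an estimated correlation (adjusted p = 0.0444). In the cholesterol and fatty acid list, 32 of 38 measured members fell and 2 rose (32 and 2 adjusted over the list alone), with a median of -0.74, adjusted p = 3.6e-06 and adjusted p = 0.0915 with an estimated correlation, including MSMO1 (-2.17) and FASN (-1.75). Of the hypoxia and glycolysis genes, 24 of 33 measured members fell and 2 rose (25 and 2 adjusted over the list alone), with a median of -0.79, adjusted p = 5.1e-04 and adjusted p = 0.413 with an estimated correlation, including BNIP3 (-2.37). Interferon response genes were higher: 17 of 32 measured members rose and 6 fell (17 and 6 adjusted over the list alone), with a median of 0.43, adjusted p = 9.8e-05 and adjusted p = 0.0511 with an estimated correlation, including OASL (1.86) and CXCL10 (1.55), but the median was 0.045, 0.11 and 0.15 without siEZH2 replicate 1, 2 or 3, where the list still passed. Among histone genes, 13 of 21 measured members rose and 3 fell (13 and 3 adjusted over the list alone), with a median of 0.60, adjusted p = 1.0e-04 and adjusted p = 0.0626 with an estimated correlation.

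In the epithelial-mesenchymal transition list, 6 of 15 measured members rose and 2 fell (6 and 2 adjusted over the list alone), with a median of 0.15, adjusted p = 0.00205 and adjusted p = 0.0621 with an estimated correlation, including VIM (2.53), THBS1 (2.52) and FN1 (2.16). Of the genes reported as repressed by EZH2, 9 of 17 measured members rose and 5 fell (9 and 5 adjusted over the list alone), with a median of 0.36, adjusted p = 0.0149 and adjusted p = 0.101 with an estimated correlation, with SOX9 (1.63) higher and the adhesion gene CDH1 (-0.99) lower. Among p53 targets, 19 of 45 measured members rose and 10 fell (19 and 11 adjusted over the list alone), with a median of 0.051, adjusted p = 0.00191 and adjusted p = 0.181 with an estimated correlation, led by SESN1 (2.49). Luminal identity genes were lower: 20 of 33 measured members fell and 6 rose (21 and 6 adjusted over the list alone), with a median of -0.41, adjusted p = 0.0376 and adjusted p = 0.151 with an estimated correlation, including KRT19 (-2.52). Of the inflammatory genes, 10 of 17 measured members rose and 5 fell (10 and 5 adjusted over the list alone), with a median of 0.29, adjusted p = 0.0308 and adjusted p = 0.319 with an estimated correlation, with NFKBIZ (1.86) higher and TNIP1 (-1.64) lower. The 5 lists that did not pass (adjusted p from 0.0543 to 0.53) included the polycomb subunits, where RYBP fell (-1.34) and JARID2 rose (1.17). The luminal call was lost without siCtrl replicate 1 or 3 or siEZH2 replicate 1 (medians -0.40, -0.42 and -0.38), and the EZH2-repressed call without siEZH2 replicate 1, 2 or 3 (0.078, 0.14 and 0.10) and with a filter at 5 (0.0094). The inflammatory call was lost without siCtrl replicate 3 or siEZH2 replicate 1, 2 or 3 (0.26, 0.26, 0.24 and 0.17), after scaling (0.43, adjusted p = 0.0971) and with no filter (0.022). With a filter at 5 the inflammatory list did not pass (median -0.51, adjusted p = 0.877), and the p53 list passed as higher with a median of -0.0069 (adjusted p = 8.6e-04). Scaling moved the medians of luminal genes to -0.24, the epithelial-mesenchymal list to 0.34 and p53 targets to 0.23 (calls kept). Without siCtrl replicate 1 the epithelial-mesenchymal median was 0.25.

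Of 11908 genes, 7538 were called, 2416 higher and 5122 lower, with 308 and 837 at least 2-fold (68.0% without overlap, 10% by chance). Median-ratio scaling moved the median of all genes by 0.167 and the share of called genes that were higher from 32.1% to 49.9%, with 6172 genes called both ways.

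In the pGIPZ experiment, shFoxA1 was compared with its own control. The sphingosine phosphate receptor gene S1PR3 rose from 3.11 ± 0.271 to 115.9 ± 1.82 RPKM (4.83 ± 0.052, adjusted p = 4.5e-14), as did the acute phase gene SAA1 (4.15), the growth factor gene TGFB3 (4.10), the keratin gene KRT16 (4.06), RGS4 (4.05) and COL23A1 (3.61). The calcium-binding protein gene S100P fell from 283 ± 16.6 to 39.98 ± 1.79 RPKM (-2.79 ± 0.065), with RLN1 (-2.51), the trefoil factor TFF1 (-2.38), the prostate secretory gene MSMB (-2.22), SNORD58C (-2.36) and SNORD54 (-2.33). The SNORD genes lie within host genes, whose reads may be counted for them. KLK3 fell from 1436 to 1279 RPKM (-0.17) and USP7 rose (0.22). EZH2 (-0.026, adjusted p = 0.605) and BUB3 (-0.047, adjusted p = 0.43) did not pass, although BUB3 did without shFoxA1 replicate 2 (-0.10, adjusted p = 0.0465).

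Interferon response genes fell: 37 of 43 measured members fell and 0 rose (38 and 0 adjusted over the list alone), with a median of -0.63 and adjusted p = 4.7e-15. OASL went from 159 to 36.7 RPKM (-2.09), with RSAD2 (-2.11) and IFIT2 (-1.82). In the epithelial-mesenchymal transition list, 12 of 19 measured members rose and 3 fell (12 and 4 adjusted over the list alone), with a median of 1.23 and adjusted p = 7.1e-06, including SNAI2 (3.10), a repressor of epithelial genes, and THBS1 (2.94). In the mitosis list, 38 of 50 measured members fell and 0 rose (41 and 0 adjusted over the list alone), with a median of -0.27 and adjusted p = 5.3e-09, from PTTG1 (-0.54) as the lowest. For DNA replication, 21 of 50 measured members fell and 0 rose (20 and 0 adjusted over the list alone), with a median of -0.15 and adjusted p = 0.00149. Of the p53 targets, 24 of 47 measured members fell and 7 rose (25 and 7 adjusted over the list alone), with a median of -0.17 and adjusted p = 0.00113, and GDF15 went from 2505 to 659 RPKM (-1.92). In the stress response list, 27 of 43 measured members fell and 10 rose (27 and 10 adjusted over the list alone), with a median of -0.20 and adjusted p = 4.4e-04, including MANF (-0.79). Of the cholesterol and fatty acid genes, 32 of 38 measured members fell and 2 rose (32 and 2 adjusted over the list alone), with a median of -0.28 and adjusted p = 9.3e-10, including the desaturase SCD (-1.01). In the forkhead and cofactor list, 21 of 27 measured members rose and 3 fell (21 and 3 adjusted over the list alone), with a median of 0.20 and adjusted p = 1.0e-04, including TLE1 (1.94) and FOXO3 (1.19).

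Of the ribosomal protein genes, 47 of 65 measured members fell and 0 rose (48 and 0 adjusted over the list alone), with a median of -0.17 and adjusted p = 4.0e-11. Among histone genes, 11 of 24 measured members rose and 0 fell (11 and 0 adjusted over the list alone), with a median of 0.31, adjusted p = 0.00666 and adjusted p = 0.0687 with an estimated correlation. In the list of stromal, immune, basal and endothelial markers, 6 of 9 measured members rose and 2 fell (6 and 2 adjusted over the list alone), with a median of 0.87, adjusted p = 0.0308 and adjusted p = 0.0892 with an estimated correlation, including ACTA2 (1.46), CD68 (1.29) and KRT14 (1.05). That call was lost without shFoxA1 replicate 1, 2 or 3 (medians 0.70, 0.71 and 0.71), with a pseudocount of 0.1 (1.28) and with no filter (0.011). The 7 other lists did not pass (adjusted p from 0.051 to 0.88). Androgen-induced genes were close to the threshold (median -0.26, adjusted p = 0.051, adjusted p = 0.235 with an estimated correlation). At the fixed correlation they passed with a pseudocount of 0.1 (-0.31), with no filter (-0.20) and without control replicate 1 or 2 (-0.225 and -0.28), with MAF (2.68) and FKBP5 (1.84) among 16 that rose. Of 12563 genes, 6186 were called, 3145 higher and 3041 lower, with 244 and 113 at least 2-fold (56.4% without overlap, 10% by chance).

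Both FOXA1 knockdowns come from libraries with no control in common. Of 12042 genes tested in both, 1927 were lower and 1334 higher in both. Independent calls would share 1362 and 756 (odds ratios 2.82 and 3.46). Both passed Fisher's exact test, which wrongly takes genes as independent units. Another 789 and 432 genes went opposite ways, and fold changes correlated across genes at r = 0.413 (rho = 0.378). THBS1 rose in both, by 3.58 and 2.94, as did IGFBP3 (4.26 and 1.87) and TLE1 (2.62 and 1.94). For shUSP7 and the pGIPZ knockdown, 1281 genes were lower and 1222 higher in both (999 and 885 if independent, r = 0.134), and 794 and 738 went opposite ways. For shBUB3 the counts were 1142 and 1208 (962 and 1028, r = 0.0898). Opposite were 889 genes lower with shBUB3 and 989 higher, the latter close to the 1003 of independent calls.

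**Figure D3:**
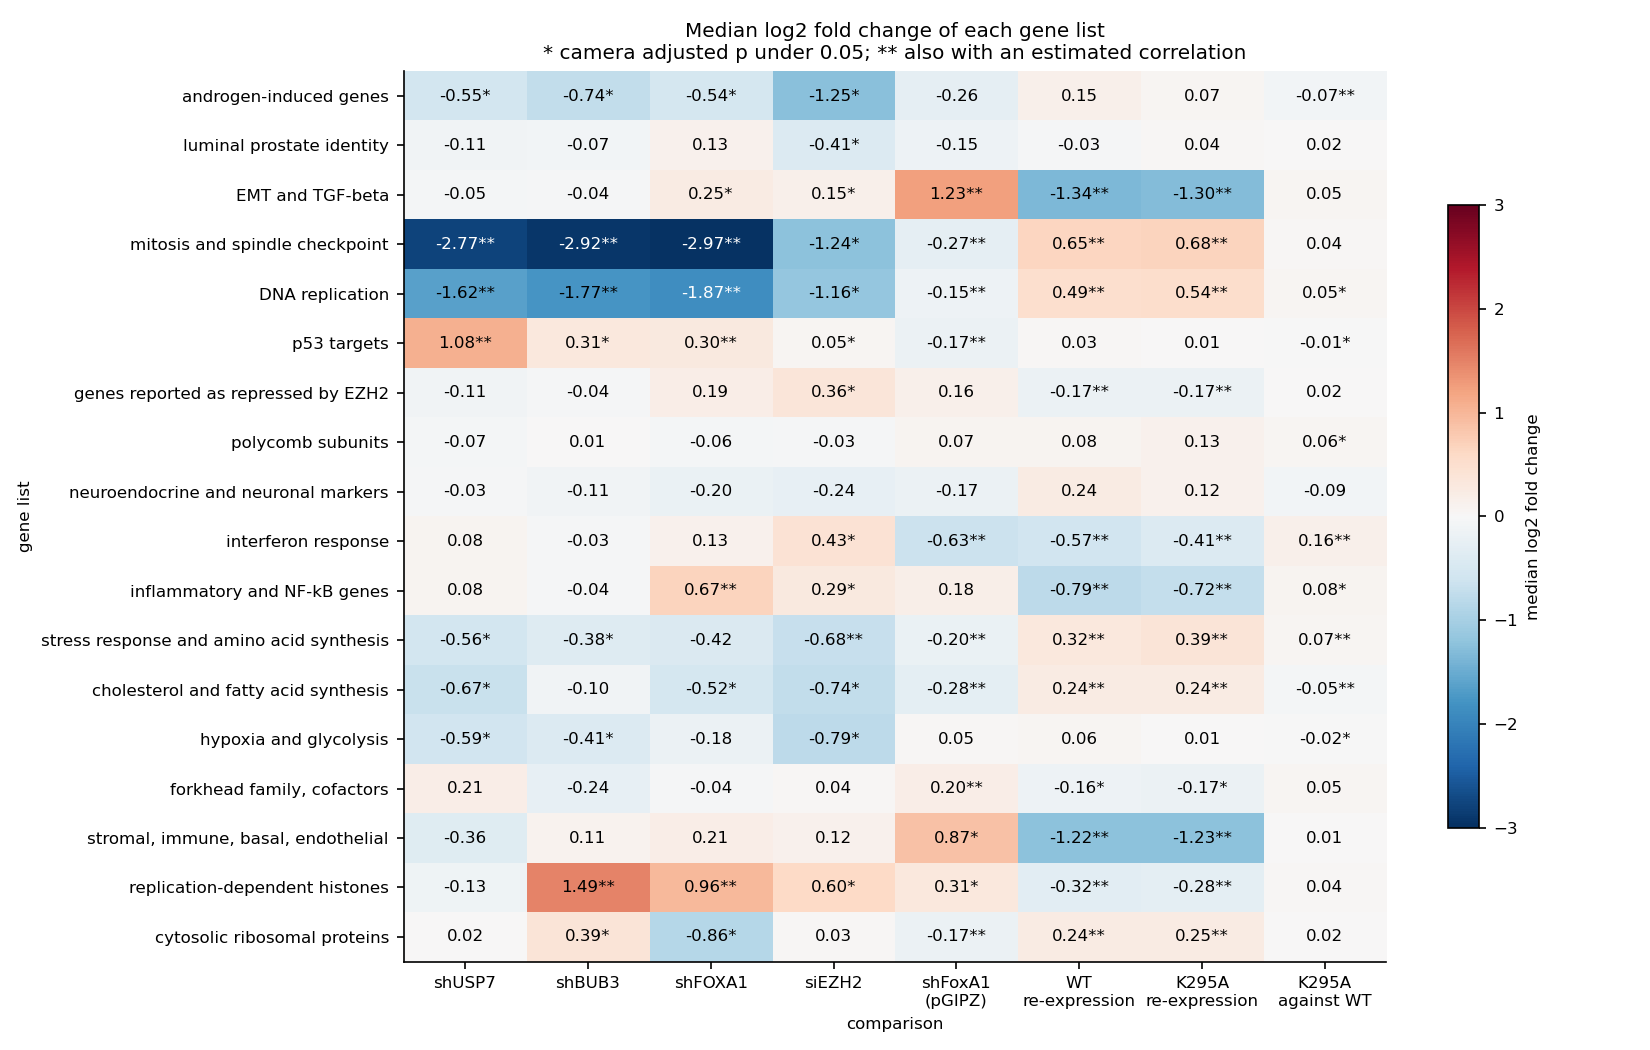
Median log2 fold change of 18 gene lists (vertical axis) in the 8 comparisons (columns), by color, where * marks a camera adjusted p under 0.05 and ** a call that also held with an estimated correlation. The mitosis list had medians of -2.77, -2.92 and -2.97 after shUSP7, shBUB3 and shFOXA1, -0.27 after shFoxA1 in the pGIPZ experiment, and 0.65 and 0.68 after re-expression of WT and K295A.

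To ask which genes respond to FOXA1, cells with shFoxA1 and WT FOXA1 were compared with cells with shFoxA1 alone. FOXA1 rose from 82.5 ± 1.87 to 152 ± 0.899 RPKM (0.87 ± 0.024, adjusted p = 7.5e-11), which counts endogenous and introduced RNA together. The transcriptional repressor gene HES6 rose from 46.0 ± 1.57 to 677 ± 18.9 RPKM (3.85 ± 0.036), with the paralogs UGT2B11 (3.77) and UGT2B28 (3.01) and with DDC (2.98). KRT16 (-4.31 ± 0.096), SAA1 (-3.83), LCN2 (-3.33) and TGFB3 (-3.30) fell most. KLK3 fell from 1279 ± 12.5 to 875 ± 13.2 RPKM (-0.55). EZH2 (0.34) and BUB3 (0.24, and 0.14 after median-ratio scaling) rose. USP7 did not pass (0.089, adjusted p = 0.0501). It turned after scaling (-0.0069) and passed with no filter or a filter at 5 (0.089 in both) and without shFoxA1 replicate 2 (0.11).

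In the epithelial-mesenchymal transition list, 13 of 19 measured members fell and 1 rose (13 and 1 adjusted over the list alone), with a median of -1.34 and adjusted p = 1.4e-09, including SNAI2 (-2.57). Every mitosis list member rose: 50 of 50 measured members rose and 0 fell (50 and 0 adjusted over the list alone), with a median of 0.65 and adjusted p = 6.9e-15, including HMMR (0.90) and NUF2 (0.88). For DNA replication, 50 of 50 measured members rose and 0 fell (50 and 0 adjusted over the list alone), with a median of 0.49 and adjusted p = 1.2e-11. Interferon response genes fell further: 34 of 43 measured members fell and 2 rose (34 and 2 adjusted over the list alone), with a median of -0.57 and adjusted p = 1.1e-13, including OAS1 (-1.83) and IFI27 (-1.76). Inflammatory genes fell: 16 of 21 measured members fell and 2 rose (17 and 2 adjusted over the list alone), with a median of -0.79 and adjusted p = 4.8e-09. Of the genes reported as repressed by EZH2, 10 of 20 measured members fell and 5 rose (10 and 5 adjusted over the list alone), with a median of -0.17 and adjusted p = 0.00246, with SOX9 (-2.67) and IGFBP3 (-2.67). In the stress response list, 30 of 43 measured members rose and 7 fell (32 and 7 adjusted over the list alone), with a median of 0.32 and adjusted p = 0.00117, while ATF3 (-0.94) and DDIT3 (-0.93) were among those that fell. Of the cholesterol and fatty acid genes, 25 of 38 measured members rose and 2 fell (26 and 2 adjusted over the list alone), with a median of 0.24 and adjusted p = 1.9e-04, with a median of 0.14 after scaling.

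In the forkhead and cofactor list, 14 of 27 measured members fell and 7 rose (15 and 7 adjusted over the list alone), with a median of -0.16, adjusted p = 0.00763 and adjusted p = 0.0511 with an estimated correlation, including TLE1 (-1.48). Of the stromal, immune, basal and endothelial markers, 7 of 9 measured members fell and 2 rose (7 and 2 adjusted over the list alone), with a median of -1.22 and adjusted p = 5.8e-04, including CD68 (-1.79) and ACTA2 (-1.55), with medians of -0.66 and -0.66 without shFoxA1 replicate 2 or 3. Among histone genes, 11 of 24 measured members fell and 0 rose (10 and 0 adjusted over the list alone), with a median of -0.32 and adjusted p = 3.7e-04. Of the ribosomal protein genes, 63 of 65 measured members rose and 0 fell (63 and 0 adjusted over the list alone), with a median of 0.24 and adjusted p = 9.9e-13. After scaling the ribosomal median was 0.14 and the forkhead and cofactor median -0.25 (calls kept). The 6 other lists did not pass (adjusted p from 0.217 to 0.88), among them androgen-induced genes (median 0.15, adjusted p = 0.88, 25 higher and 16 lower of 46). Of 12563 genes, 6970 were called, 4593 higher and 2377 lower, with 140 and 269 at least 2-fold (61.7% without overlap, 10% by chance). Median-ratio scaling moved the share of called genes that were higher from 65.9% to 49.1%, with 5606 genes called both ways.

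The same comparison was made for K295A. FOXA1 stood at 151.4 ± 2.90 RPKM (0.87 ± 0.024, adjusted p = 8.0e-11). UGT2B11 (3.79 ± 0.051), HES6 (3.64), UGT2B28 (2.97) and DDC (2.93) rose most, and KRT16 (-4.18 ± 0.096), SAA1 (-3.66), TGFB3 (-3.22) and the protease inhibitor gene PI3 (-3.11) fell most. KLK3 fell to 832.6 RPKM (-0.62), and the glucocorticoid-induced TSC22D3 rose (2.05). EZH2 (0.47) and BUB3 (0.32, and 0.20 after median-ratio scaling) rose. USP7 rose (0.13) and did not pass after scaling (0.020, adjusted p = 0.662).

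In the epithelial-mesenchymal transition list, 13 of 19 measured members fell and 1 rose (13 and 1 adjusted over the list alone), with a median of -1.30 and adjusted p = 1.0e-09, including SNAI2 (-2.90). All mitosis and replication genes rose: for mitosis 50 of 50 measured members rose and 0 fell (50 and 0 adjusted over the list alone), with a median of 0.68 and adjusted p = 1.1e-14, and for replication 50 of 50 measured members rose and 0 fell (50 and 0 adjusted over the list alone), with a median of 0.54 and adjusted p = 6.8e-12. In the interferon list, 32 of 43 measured members fell and 4 rose (32 and 5 adjusted over the list alone), with a median of -0.41 and adjusted p = 4.5e-10. Inflammatory genes fell: 16 of 21 measured members fell and 2 rose (16 and 2 adjusted over the list alone), with a median of -0.72 and adjusted p = 1.1e-08, including LCN2 (-2.999). Of the genes reported as repressed by EZH2, 9 of 20 measured members fell and 5 rose (9 and 5 adjusted over the list alone), with a median of -0.17 and adjusted p = 0.00142. In the stress response list, 31 of 43 measured members rose and 7 fell (31 and 7 adjusted over the list alone), with a median of 0.39 and adjusted p = 5.1e-04, including the serine synthesis gene PSAT1 (1.06). Of the cholesterol and fatty acid genes, 25 of 38 measured members rose and 2 fell (25 and 3 adjusted over the list alone), with a median of 0.24 and adjusted p = 0.00666, with a median of 0.13 after scaling (adjusted p = 0.0355). In the forkhead and cofactor list, 13 of 27 measured members fell and 7 rose (14 and 8 adjusted over the list alone), with a median of -0.17, adjusted p = 0.0109 and adjusted p = 0.057 with an estimated correlation, with a median of -0.28 after scaling. Of the stromal, immune, basal and endothelial markers, 7 of 9 measured members fell and 2 rose (7 and 2 adjusted over the list alone), with a median of -1.23 and adjusted p = 3.5e-04, with medians of -0.77, -0.60 and -0.60 without shFoxA1 replicate 1, 2 or 3.

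Among histone genes after K295A, 11 of 24 measured members fell and 0 rose (11 and 0 adjusted over the list alone), with a median of -0.28 and adjusted p = 3.5e-04. Of the ribosomal protein genes, 63 of 65 measured members rose and 0 fell (63 and 0 adjusted over the list alone), with a median of 0.25 and adjusted p = 9.9e-13, with a median of 0.14 after scaling. The 6 other lists did not pass (adjusted p from 0.188 to 0.925). Of 12563 genes, 7151 were called, 4858 higher and 2293 lower, with 146 and 260 at least 2-fold (63.6% without overlap, 10% by chance). Median-ratio scaling moved the median of all genes by -0.101 and the share of called genes that were higher from 67.9% to 48.5%, with 5498 genes called both ways.

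To ask whether changes after shFOXA1 turned around in separate libraries, genes at least 2-fold changed in the pLKO experiment were followed through re-expression. Of 1104 measured genes of the lower set, 913 rose and 32 fell with WT (median 0.43 against 0.06 in other genes, camera adjusted p = 1.7e-26 over 12 set tests, adjusted p = 8.6e-06 with an estimated correlation). With K295A, 937 rose and 35 fell (median 0.44, adjusted p = 5.7e-26 and 8.6e-06 with an estimated correlation). Of 499 measured genes of the higher set, 341 fell and 29 rose with WT (median -0.43, adjusted p = 2.0e-37) and 346 fell and 27 rose with K295A (median -0.41, adjusted p = 4.5e-40). Their adjusted p was 2.8e-06 in both with an estimated correlation. Between K295A and WT neither set passed (medians 0.03 and 0.00, adjusted p = 0.725 and 0.524).

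Genes at least 2-fold changed in the pGIPZ knockdown were followed through the other knockdowns. After siEZH2, the higher set had a median of 0.17 against -0.16 in other genes, with 76 of 159 measured genes higher and 48 lower (adjusted p = 2.0e-05, adjusted p = 0.134 with an estimated correlation), and the lower set did not pass (-0.12, adjusted p = 0.308). With sets of any fold the higher set did not pass (-0.15 against -0.16 in other genes, adjusted p = 0.617). After shBUB3, the higher set was lower (-0.15, 52 higher and 89 lower, adjusted p = 0.0381, adjusted p = 0.316 with an estimated correlation), a call lost without shBUB3 replicate 3 (-0.14) and with sets of any fold (0.077, adjusted p = 0.115). The lower set was at -0.22 (adjusted p = 0.0513) and passed without shBUB3 replicate 2 (-0.30) at the fixed correlation, with adjusted p = 0.316 over all libraries at the estimated one. After shUSP7 neither set passed (0.078 and 0.067, adjusted p = 0.308 and 0.126).

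**Figure D4:**
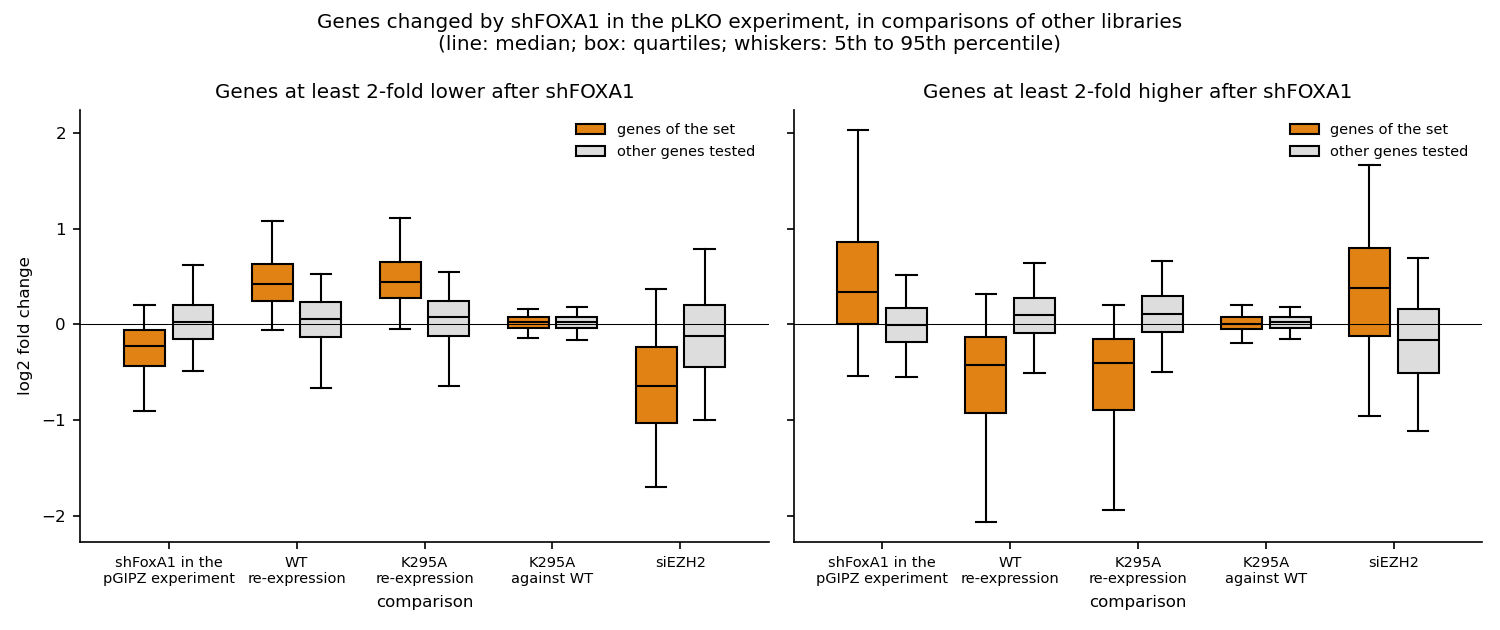
Log2 fold changes of genes at least 2-fold lower or higher after shFOXA1 in the pLKO experiment and of other genes, in shFoxA1 of the pGIPZ experiment, WT, K295A, K295A against WT and siEZH2 (line, median; box, quartiles; whiskers, 5th to 95th percentiles). The lower set had medians of 0.43 with WT, 0.44 with K295A and -0.65 with siEZH2, and the higher set -0.43, -0.41 and 0.38, where the siEZH2 comparison was chosen after seeing the data.

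To ask what the lysine changes, K295A was compared with WT directly. FOXA1 (-0.0042, adjusted p = 0.972) did not pass the test, nor did KLK3 (-0.071, adjusted p = 0.122), which passed after median-ratio scaling (-0.090, adjusted p = 0.0255). USP7 (0.044), BUB3 (0.079) and EZH2 (0.13) did not pass (adjusted p = 0.722, 0.595 and 0.24). Interferon-induced genes were higher with K295A: IFIT3 went from 4.29 ± 0.0869 to 6.89 ± 0.420 RPKM (0.58 ± 0.048, adjusted p = 9.1e-04), IFIT2 from 7.81 ± 0.685 to 11.8 ± 0.848 (0.54 ± 0.065, adjusted p = 0.00693) and OASL from 30.5 ± 0.901 to 41.3 ± 1.37 (0.43 ± 0.039, adjusted p = 0.00126). MSMB also rose (0.68 ± 0.12, adjusted p = 0.0498). Androgen-induced TMPRSS2 (-0.16 ± 0.019) fell slightly, as did GDF15 (-0.15, a call lost with no filter, adjusted p = 0.11) and TARP (-0.41). Of the small RNA genes, SNORD5 fell from 12.9 ± 0.548 to 6.01 ± 1.54 RPKM (-1.01), MIR6759 fell (-1.88) and MIR421 was listed at 0 in every K295A library against 3.35 ± 1.41 with WT.

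As lists, interferon response genes were higher: 5 of 43 measured members rose and 0 fell (19 and 1 adjusted over the list alone), with a median of 0.16 and adjusted p = 4.3e-14. Androgen-induced genes were lower: 2 of 46 measured members fell and 0 rose (17 and 0 adjusted over the list alone), with a median of -0.071 and adjusted p = 9.5e-13. Cholesterol and fatty acid genes (median -0.049, adjusted p = 9.9e-08), the stress response list (median 0.068, adjusted p = 0.00214), the inflammatory list (median 0.081, adjusted p = 0.0177, adjusted p = 0.057 with an estimated correlation) and DNA replication (median 0.052, adjusted p = 0.0275, adjusted p = 0.0511 with an estimated correlation) also passed, each with 0 members called over all genes. So did hypoxia and glycolysis (median -0.021, adjusted p = 0.0111, adjusted p = 0.107 with an estimated correlation), p53 targets (median -0.0057, adjusted p = 0.0356, adjusted p = 0.0584 with an estimated correlation) and polycomb subunits (median 0.058, adjusted p = 0.0434, adjusted p = 0.0744 with an estimated correlation). Adjusted over the list alone, 2 cholesterol genes, 2 hypoxia genes and 4 p53 targets fell, and over all genes tested 0, 0 and 1 did. The 9 further lists did not pass (adjusted p from 0.0577 to 0.88). Neuroendocrine and neuronal markers passed in none of the 8 comparisons (adjusted p from 0.141 to 0.925), with a median of -0.086 here. Mitochondrially encoded genes had 0 measured members.

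Of 12563 genes, 23 were called between K295A and WT, 11 higher and 12 lower, with 3 at least 2-fold lower, and 1310 genes had an unadjusted p under 0.05 (16.0% without overlap, 10% by chance). Median-ratio scaling gave 30 calls, 33.3% of them higher against 47.8%. A fit of these 2 groups alone gave 6 calls and none of IFIT2, MSMB, TARP, SNORD5, MIR6759 and TMPRSS2, and leaving out a library gave 9 to 18. The MSMB, MIR6759 and TARP calls were lost in most of those fits, and SNORD5 without WT replicate 2 (-0.9998). List calls lost without a library were replication without WT replicate 1 or 3 or K295A replicate 2 (0.052, 0.048 and 0.044), p53 without WT or K295A replicate 1 or 3 (-0.019, -0.0090, -0.015 and -0.0012), and hypoxia without WT replicate 2 or K295A replicate 1 (-0.015 and -0.012). Calls that held had medians of -0.0092 and -0.015 for p53 without replicate 2 of WT or K295A, -0.0075, -0.013 and -0.012 for hypoxia without WT replicate 1 or K295A replicate 2 or 3, 0.043 for stress response without WT replicate 2 and -0.031 for cholesterol without K295A replicate 2. After scaling they were 0.034 for replication, -0.023 for p53 and -0.039 for hypoxia. The replication (0.053), polycomb (0.055) and p53 (0.0088) calls were lost with a filter at 5, and that of p53 with no filter (-0.0040). The polycomb call was lost without WT replicate 1, 2 or 3 or K295A replicate 1 or 3 (0.027, 0.050, 0.068, 0.042 and 0.036) and after scaling (0.042).

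**Figure D5:**
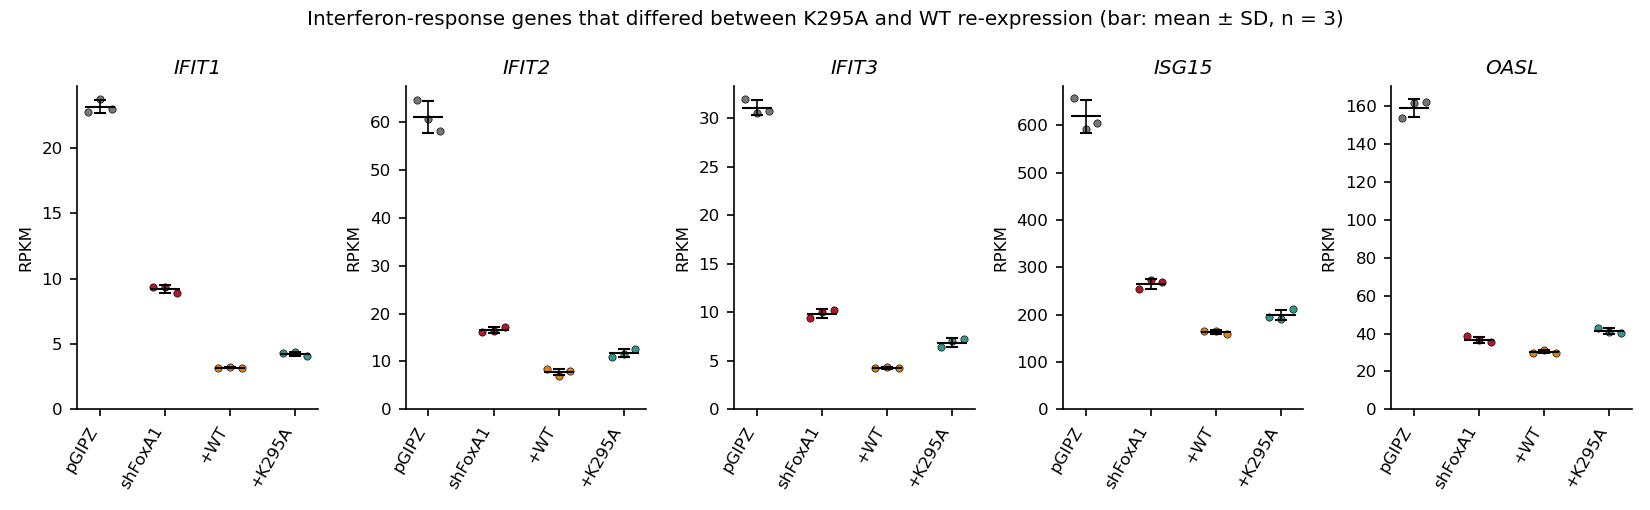
RPKM of IFIT1, IFIT2, IFIT3, ISG15 and OASL in each library of the pGIPZ experiment (points) by group, where IFIT1 and ISG15 were chosen after their values were seen. IFIT3 averaged 4.29 RPKM with WT and 6.89 with K295A, against 9.38 to 10.2 after shFoxA1 alone and 30.5 to 32.0 in the control libraries.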

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

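The tests of a deeper FOXA1 knockdown and of the difference between the FOXA1 knockdowns were chosen only after the data had been seen, and the other tests here were set before.

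In the FOXA1 knockdowns of the pLKO and the pGIPZ experiment, the following stood on opposite sides of 0 in 3 of 3 libraries each. USP7 was called in both, at -0.35 and 0.22. For lists, the median change of members measured in both experiments was averaged over the libraries. Luminal identity genes stood at 0.13 and -0.13, p53 targets at 0.31 and -0.19, and polycomb subunits at -0.091 and 0.053. Interferon response genes stood at 0.10 and -0.61, hypoxia and glycolysis genes at -0.22 and 0.028, and forkhead genes and cofactors at -0.015 and 0.22. Of these lists only p53 targets passed the camera test in both experiments. Luminal identity (adjusted p = 0.0531 and 0.079), polycomb subunits (0.622 and 0.217) and hypoxia and glycolysis (0.565 and 0.318) passed in neither, and interferon response (0.0705 in the pLKO experiment) and forkhead genes and cofactors (0.493) only in the pGIPZ experiment. Relative to the median of all genes in each library, polycomb subunits (0.073 and 0.050) and forkhead genes and cofactors (0.15 and 0.21) were no longer opposite, and after median-ratio scaling hypoxia and glycolysis genes turned to 0.0047 in the pLKO experiment.

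The difference between the FOXA1 knockdowns, pLKO minus pGIPZ experiment, was tested for 4 genes with limma errors and for 18 lists with libraries as units (Welch's t-test), adjusted over 22 tests. It passed for 21 (adjusted p from 2.8e-08 to 0.00644) and not for genes reported as repressed by EZH2 (-0.038, adjusted p = 0.373). For genes it was -0.57 for USP7 (95% interval -0.71 to -0.44), -1.12 for BUB3, -0.96 for EZH2 and -0.35 for KLK3. For lists it was 0.26 for luminal identity, 0.49 for p53 targets, 0.71 for interferon response, 0.62 for inflammatory genes and 0.40 for histones. It was -0.33 for androgen-induced genes, -0.79 for the epithelial-mesenchymal list, -1.74 for DNA replication, -0.14 for polycomb subunits, -0.40 for neuroendocrine markers and -0.24 for stress response. It was -0.25 for cholesterol and fatty acid synthesis, -0.24 for hypoxia and glycolysis, -0.23 for forkhead genes and cofactors, -0.38 for stromal, immune, basal and endothelial markers and -0.69 for ribosomal proteins. Relative to the median of all genes, with libraries as units throughout, it did not pass for polycomb subunits (0.023, adjusted p = 0.366), forkhead genes and cofactors (-0.063, adjusted p = 0.0658) and stress response (-0.073, adjusted p = 0.0546). It then passed for genes reported as repressed by EZH2 (0.13, adjusted p = 0.0135). The experiments differ in vector and table, and these tests do not part these from the knockdown. Control levels may differ too: OASL of the interferon list averaged 159 RPKM in the pGIPZ control and 0.468 FPKM in the pLKO control.

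The mitosis list fell in both FOXA1 knockdowns, by -2.97 (pLKO) and -0.27 (pGIPZ). The difference by Welch's t-test was -2.68 (-2.77 to -2.59, adjusted p = 2.8e-08). Control libraries with unusually high mitosis genes are argued against, since the pLKO control differed from siCtrl in the same table by a median of -0.023 (95% interval -0.065 to 0.037). A deeper knockdown of FOXA1 in the pLKO experiment could contribute: the FOXA1 log2 change differed by -0.30 (-0.47 to -0.12). Relative to all genes (medians -0.15 in pLKO, 0.0011 in pGIPZ) this shrinks, and was not tested. Graded FOXA1 levels were not measured. Vectors, shRNA sequences and effects of either shRNA on other genes stay open as untested.

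K295A and WT differed in 9 lists by camera in their direct comparison. Medians were -0.071 for androgen-induced genes, 0.052 for DNA replication, -0.0057 for p53 targets, 0.058 for polycomb subunits and 0.16 for interferon response. They were 0.081 for inflammatory genes, 0.068 for stress response, -0.049 for cholesterol and fatty acid synthesis and -0.021 for hypoxia and glycolysis. With an estimated correlation, androgen-induced genes, interferon response, stress response and cholesterol and fatty acid synthesis passed. DNA replication, p53 targets, polycomb subunits, inflammatory genes and hypoxia and glycolysis did not (adjusted p = 0.0511, 0.0584, 0.0744, 0.057 and 0.107).

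Few genes were called between K295A and WT, 23 of 12563. Low precision could hide changes, and 79.4% of genes simulated at 1.5-fold were recovered (95% interval 74.7 to 83.6). This leaves open how many smaller changes were missed, since 47.2% were recovered at the smallest size simulated. A small effect of the K295A change on RNA stays open as the biological explanation and was not tested further.

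Other divisions of the 6 libraries of each comparison into 3 and 3 were refitted in fits of 2 groups. With 10 divisions the share cannot go under 0.1. In each comparison 1 division, the real one itself, reached the real count. The real counts were 9030 for shUSP7, 6946 for shBUB3, 9554 for shFOXA1, 7538 for siEZH2, 5778 for shFoxA1 in the pGIPZ experiment, 6696 for WT and 6956 for K295A, with 0 as the highest of the other divisions. For K295A against WT it was 6, with 2 as the highest of the others.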

How the results depend on the processing

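The size of at least 1.5-fold was an alternative chosen after seeing the data, and the others were set before. Each targeted gene in its own knockdown, and FOXA1 in both re-expression comparisons, kept direction and call under all alternatives run, including 42 of 42 fits that left out a library. Counts of called genes stayed within 1.5 times their value under scaling, the pseudocount and the filter at 5 in 8 of 8 comparisons. Of 144 list tests, 139 kept their direction and side of the threshold under median-ratio scaling, 141 with a pseudocount of 0.1, 137 with no filter and 143 with a replicate block. With an estimated correlation 110 of 144 did and 34 lost their call. Leaving out a library kept 820 of 864. Of the named genes, 428 of 434 were the same under scaling and 2489 of 2523 without a library. Lists that came to pass without a library included luminal identity in shFOXA1 without shFOXA1 replicate 1, 2 or 3 (0.17, 0.11 and 0.12) and interferon response in shFOXA1 without control replicate 1, 2 or 3 (0.16, 0.17 and 0.18). In siEZH2 they were ribosomal proteins without siCtrl replicate 3 or siEZH2 replicate 1, 2 or 3 (0.074, 0.021, 0.015 and 0.036) and forkhead genes without siEZH2 replicate 2 (0.067). In K295A against WT they were the epithelial-mesenchymal list without WT replicate 1 or K295A replicate 3 (0.067 and 0.075) and ribosomal proteins without replicate 2 of either group (0.028 and 0.019). Under other alternatives, ribosomal proteins passed in siEZH2 after scaling (0.22), with the filter at 5 (0.026) and with a replicate block (0.025), and forkhead genes with the filter at 5 (0.053). The epithelial-mesenchymal list passed in K295A against WT after scaling (0.031), with the filter at 5 (0.080) and in a fit of 2 groups (0.076). With no filter, stress response passed in shFOXA1 (-0.37) and luminal identity in the pGIPZ knockdown (-0.17). Genes reported as repressed by EZH2 passed in shBUB3 with the filter at 5 (-0.36) and in both FOXA1 knockdowns in fits of 2 groups (0.26 and 0.24). With all libraries and an estimated correlation none of these lists passed. Same-numbered libraries did not pair, since at most 1 of 3 pairs in any 2 groups correlated above 0.1 in their deviations.

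At least 1.5-fold, the counts were 3036 for shUSP7, 3306 for shBUB3, 4221 for shFOXA1, 3348 for siEZH2, 1088 for shFoxA1 in the pGIPZ experiment, 1342 for WT, 1384 for K295A and 4 for K295A against WT, lower by construction. The 23 calls of K295A against WT became 11 with no filter, 6 in a fit of 2 groups, 14 with a replicate block and 9 to 18 without a library. Fewer libraries or degrees of freedom enter the last 3.

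The shFOXA1 median of the epithelial-mesenchymal list was 0 with no filter, which adds genes at 0. With no filter 22 called lists kept their call and 2 lost it with a median over 1.5 times closer to 0. With the filter at 5, which leaves fewer members, the p53 median was -0.0069 in siEZH2, where the list still passed as higher (adjusted p = 8.6e-04), and 0.0088 in K295A against WT, where it did not pass. The inflammatory list did not pass in siEZH2 (-0.51, adjusted p = 0.877). That filter also moved medians of calls that held by over 1.5 times: the epithelial-mesenchymal list (0.89 in shFOXA1 and 0.67 in siEZH2), inflammatory genes (0.29 in shFOXA1 and 0.14 in K295A against WT), histones (0.50 in the pGIPZ knockdown and -0.49 in K295A) and genes reported as repressed by EZH2 (-0.65 in WT and -0.35 in K295A). A pseudocount of 0.1 did so for stromal, immune, basal and endothelial markers in WT (-1.89) and interferon response in K295A against WT (0.24).

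For the sets from the pGIPZ FOXA1 knockdown, the lower set in shBUB3 passed with a pseudocount of 0.1 (-0.40), the filter at 5 (-0.24), a fit of 2 groups (-0.27) and a replicate block (-0.22), with -0.30 to -0.14 without a library. The higher set in shBUB3 did not pass with the filter at 5 (-0.11), a fit of 2 groups (-0.16) or an estimated correlation (-0.15), with -0.18 to -0.14 without a library. In siEZH2 the higher set moved to 0.32 after scaling (call kept) and did not pass with an estimated correlation (0.17). With sets of any fold, the lower set in shUSP7 turned to -0.12 and passed, as did the higher set (0.089). Both calls were lost with an estimated correlation (adjusted p = 0.462 and 0.502). Higher sets of any fold did not pass in shBUB3 (0.077) or siEZH2 (-0.15). The causes of these set changes were not tested.

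Genes lower in both shUSP7 and shBUB3 came to 1428 with the filter at 5, which tests fewer genes. With the pGIPZ FOXA1 knockdown in place of that of the pLKO experiment, 1281 genes were lower with shUSP7 and 1142 with shBUB3, from fewer calls. Recovery of genes simulated at the smallest size was lowest in the siRNA experiment, which also had the lowest relative depth in its table.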

Other observations

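The comparisons with the pGIPZ control, the test of the pLKO FOXA1 sets in siEZH2 and the scores of words without a shared 6-base run were chosen after the data had been seen. The seed tests were set after the word scan had been seen and before their own values were.

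Cells with re-expressed FOXA1 were also compared with the pGIPZ control. With WT, 5716 of 12563 genes were called by limma, 4228 higher and 1488 lower, and 168 changed at least 2-fold. With K295A, 6350 were called, 4744 higher and 1606 lower, and 160 changed at least 2-fold. Interferon response genes were lower than in the control, with 39 of 43 lower with WT (median -1.30, camera adjusted p = 5.6e-41, adjusted p = 5.5e-06 with an estimated correlation) and 38 with K295A (median -1.26, adjusted p = 5.2e-37). Mitosis genes were higher than in the control, at medians of 0.37 with WT (adjusted p = 1.3e-10) and 0.41 with K295A (adjusted p = 2.6e-10). DNA replication genes stood at 0.33 and 0.40, luminal identity genes at -0.20 and -0.18.

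Genes changed in pLKO shFOXA1 were followed through siEZH2. Of 1097 measured genes at least 2-fold lower after shFOXA1, 826 fell and 75 rose after siEZH2 (median -0.65 against -0.12 in other genes, camera adjusted p = 3.0e-14 over 2 tests, adjusted p = 0.126 with an estimated correlation). Of 440 measured genes that were higher, 247 rose and 94 fell (median 0.38, adjusted p = 1.2e-14, 0.0522 with an estimated correlation). Mitosis and replication genes fell in both knockdowns and were not set apart. Of the pGIPZ sets, only the higher passed here.

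MIR30A, a microRNA gene, averaged 973.9 ± 75.7 RPKM in the pGIPZ control (n = 3), 2211 ± 88.5 after shFoxA1, 1432 ± 17.5 with WT and 1407 ± 13.2 with K295A. It was chosen after its values were seen. The pGIPZ vector expresses its shRNA within a microRNA-30 backbone, and the tables do not show whether reads came from the vector or the gene.

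In the word scan of 3′ UTRs, the lowest 7-base word scored below the lowest of 100 permutations in each of the 5 knockdowns (p = 0.0099, the smallest these can give). After siEZH2 it was GAGCTGA (score -13.2, lowest in permutations -4.40), after shUSP7 TATCAAA (-8.45, -4.91) and after shBUB3 CAGATGC (-12.3, -4.76). Genes with the 8-base site, the 7-base word, the 6-base core alone and no core had medians of -0.47, -0.26, -0.14 and -0.14 after siEZH2, -0.15, -0.081, -8.5e-05 and 0.017 after shUSP7, and -0.17, -0.11, 0.0090 and 0.081 after shBUB3. In GRCh38, GAGCTGA lay in a coding exon of EZH2 (chromosome 7, 148847192 to 148847198), TATCAAA in coding exons of USP7 (chromosome 16, 8899623 to 8899629 and 8915267 to 8915273), and CAGATGC in a coding exon of BUB3 (chromosome 10, 123162807 to 123162813) and in its 3′ UTR (123169432 to 123169438). The 8-base site was in 3 BUB3 transcripts and in 0 transcripts of EZH2 and of USP7. After shFOXA1 the lowest word was GAGGGTT (-6.47, -4.51), found in 1 of 5 FOXA1 transcripts. After shFoxA1 in the pGIPZ experiment it was AATCCCA (-4.61, -4.37), found in 2 of 5, although genes with it had a median of 0.021 against 0.00039 in the others. The lowest scores with WT, K295A and K295A against WT were within their permutations (p = 0.604, 0.376 and 0.356).

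A candidate explanation is silencing of other transcripts by the seed of the siRNA or shRNA, whose sequences the labels do not give. It needs the word in the targeted transcript, and it occurred in 9 of 10 annotated EZH2 transcripts, 11 of 21 USP7 transcripts and 3 of 5 BUB3 transcripts, where 22.6%, 36.5% and 36.2% of all scored words occur. Passing the scan does not show a seed. The FOXA1 words were not tested further, and a seed stays open: GAGGGTA (-5.29), AGAGGGT (-5.22) and TGAGGGT (-4.65) share GAGGGT with that of shFOXA1. Base composition of the UTR as the whole cause is argued against for siEZH2 and shBUB3. The most extreme other words of the same bases that hold no 6-base run of the 8-base site scored -4.19 and -3.56, and their excess over 0.5 of the leading score had intervals of 0.77 to 4.203 and 0.71 to 4.55. With words left out for the core alone, AGAGCTG and CCAGATG scored -5.95 and -4.84, with intervals that include 0 (-1.001 to 2.54 and -0.55 to 3.11), and both hold another 6-base run of the site. After shUSP7 neither choice of words decides on base composition, since both intervals include 0 (-4.26, -1.64 to 1.55, and -3.94, -1.48 to 2.21). Seed sites as the cause of the lower mitosis list are argued against, since members without the core had medians of -2.77 after shUSP7 (-2.87 to -2.51) and -2.91 after shBUB3 (-3.22 to -2.71). For androgen-induced genes after siEZH2 both stay open, with -1.16 in 22 members without the core (-1.78 to -0.82) and -1.81 in those with it.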
